A study of Mus musculus with 8 samples.

How the data were processed

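Ovarian RNA from mice of 33 weeks was profiled on 8 one-colour Agilent mouse gene expression arrays, 3 of wildtype ovary and 5 of ovarian neoplasia. Per the labels, total RNA from flash-frozen ovaries of cycling mice was labelled with Cy3. All 8 arrays lay on 1 slide and were scanned in 1 session. The first slide row held neoplasia 1 to 4. The second row held neoplasia 5 and the 3 wildtype arrays. The genotype of the neoplasia mice is written in 2 ways in the labels, and both name a cre allele of Pgr together with an LsL allele of the progesterone receptor. The sample titles number the replicates within a group, whereas another label field calls each sample replicate 1, and the titles were followed. No label says that each array came from a separate animal, so the p-values measure the spread between these samples.

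The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the file headers. The processed intensity was background-subtracted and spatially detrended by that software and was not normalized between arrays. The grid was annotated on mm9 per the file headers. The deposited value table of the series holds log2 values. Each of its 37932 rows matched log2 of the mean processed intensity over all spots with the same feature name within 0.001, so its scale is log2, it was not centred, and no array was turned. Its medians were 6.03, 6.07 and 5.75 in the wildtype arrays and 4.80, 5.37, 5.21, 4.99 and 5.33 in neoplasia 1 to 5. The submitters' processing notes name Partek, without its role.

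Each array had 62976 spots, of which 59305 were not controls and held 55681 distinct probes. The main values were log2 of the processed intensity minus the array's 75th percentile of it. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. Probes well above background on at least 3 arrays were tested, and the probe with the highest mean over all arrays stood for a gene. No probe was saturated. The files give accessions and no gene names. Accessions without their versions were matched to the RefSeq table of GRCm38.p6, which named 26582 of the 55681 probes (47.7%) with 20145 symbols. The other features, among them 16194 probes of genomic intervals, were tested under the names in the files. Neither probe sequences nor probe positions within a transcript were used here, so the part of a gene that a probe covers is not stated.

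Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, 6 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested features at 0.05. Fold changes are neoplasia over wildtype, on the log2 scale with their standard errors. A gene not well above background on any array of a group has only a bound there. Such a fold is given as "at least", from the mean of the brighter group and, for the dimmer group, the mean over arrays of the higher of the probe's own value and the lowest signal among probes well above background. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists, with camera at an estimated correlation and fry beside it. The 22 lists held 443 entries, of which 431 had a symbol on the array. Measures of whole arrays were compared with an exact permutation test over all 56 splits of the 8 arrays into 3 and 5, two-sided.

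The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes Pgr with each of its probes, the 10 largest rises and the 10 largest falls among genes with a usable symbol whose groups did not overlap, and up to 4 changed members of each list by the size of their change. Of the 96 genes it gives, 2 are not reported here. Alternatives fixed at the same time were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter that needs all 8 arrays above background, the authors' deposited log2 values, the mean over the probes of a gene, eBayes with trend and robust, array weights, the replicate number as a block, a stricter threshold of 0.01, a linear model without moderation, and leaving out each array. The scanner files used here have no mean foreground intensity, so normexp was run on the median foreground and background intensity. Scaling on the E1A spike-in controls (5 of 10 spike-in probes above background on all arrays), slide row as a block, slide row 2 alone and an exact permutation test of list means were added after the data were seen, as were 9 further marker lists (uterus, decidua and placenta, liver, epididymis and seminal vesicle, adrenal cortex, kidney, pancreas, erythroid progenitor, and neutrophil and platelet). Slide row 2 alone sets 1 neoplasia array against the wildtype arrays, so its tests hold no spread between neoplasias.

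The gene test was tested on 5 simulated data sets of 25170 genes with 200 changed genes each, drawn from the spread of the real arrays. It recovered 11.2% of changes of 1 on the log2 scale, 59.2% of changes of 2, 89.6% of changes of 4 and 95.6% of changes of 6, and 5.80% of its calls were false. These draws had independent genes and 1 spread per gene for both groups. In the real arrays the neoplasias varied more and 7635 features changed, so these shares need not hold there. In simulated sets with independent genes, camera called the shifted set in 5 of 5 draws and 0 of 105 unshifted sets. Arrays carry no counting depth, and the number of arrays limits the precision.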

Results

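Samples of wildtype ovary on 3 arrays and of ovarian neoplasia on 5 arrays were compared, from mice of 33 weeks of age. The neoplasia mice carried cre at the Pgr locus, which encodes the progesterone receptor, and an LsL allele of the receptor, which 1 of the 2 forms of the genotype in the labels writes as isoform B. An LsL allele holds a stop cassette between loxP sites and is expressed after Cre has removed it. The comparison asked how the RNA profile of these neoplasias differed from that of the cycling wildtype ovary. Neither the stage of the cycle nor the cell content of the samples is given in the labels.

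Wildtype arrays were close to each other, and the neoplasias were more varied. Over pairs of wildtype arrays, the SD of log2 differences between probes was 0.34 to 0.55, against 0.72 to 1.06 within the neoplasias and 1.02 to 1.36 between the groups. The first principal component held 61.2% of the variance and separated the groups, with neoplasia 5 nearest to the wildtype arrays. The 75th percentile of signal was 496 ± 29.4 (SD, n = 3) in wildtype and 359 ± 44.2 (SD, n = 5) in neoplasia arrays (exact permutation p = 0.0179, adjusted p = 0.0357 over 4 measures). Probes well above background numbered 33913 ± 247 (SD, n = 3) and 30746 ± 1580 (SD, n = 5) of 55681 (exact permutation p = 0.0357, adjusted p = 0.0476). The 100 brightest spots held 13.7% ± 0.188 (SD, n = 3) and 15.5% ± 0.429 (SD, n = 5) of the signal (exact permutation p = 0.0179, adjusted p = 0.0357). Spike-in controls averaged 10.07 ± 0.05 (SD, n = 3) and 10.20 ± 0.77 (SD, n = 5) on the log2 scale (exact permutation p = 0.839, adjusted p = 0.839). They lay at 8.89 on neoplasia 1 and at 10.19 to 10.75 on neoplasia 2 to 5. Scaling on them therefore shifts the neoplasia arrays against each other by these differences.

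The 2 probes of Pgr moved in opposite directions. Probe A_51_P213476 rose from -5.22 ± 1.73 (SD, n = 3) in wildtype to 3.91 ± 0.73 (SD, n = 5) in neoplasia, a difference of 9.13 ± 0.73 (SE) on the log2 scale or 559-fold (limma adjusted p = 0.000133). It was well above background on 2 of 3 wildtype arrays and on 5 of 5 neoplasia arrays, where the signal lay between 3128 and 10660. The difference was 8.13 without wildtype 3, on which the probe was not well above background, 6.29 with normexp and 6.38 in the authors' values. Probe A_55_P2095663 was well above background on 3 of 3 wildtype arrays and on 0 of 5 neoplasia arrays, and was at least 2.88-fold lower in the neoplasia (limma adjusted p = 0.00337). The mean over both probes was 2.70 higher on the log2 scale (adjusted p = 0.0151).

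**Figure D1:**
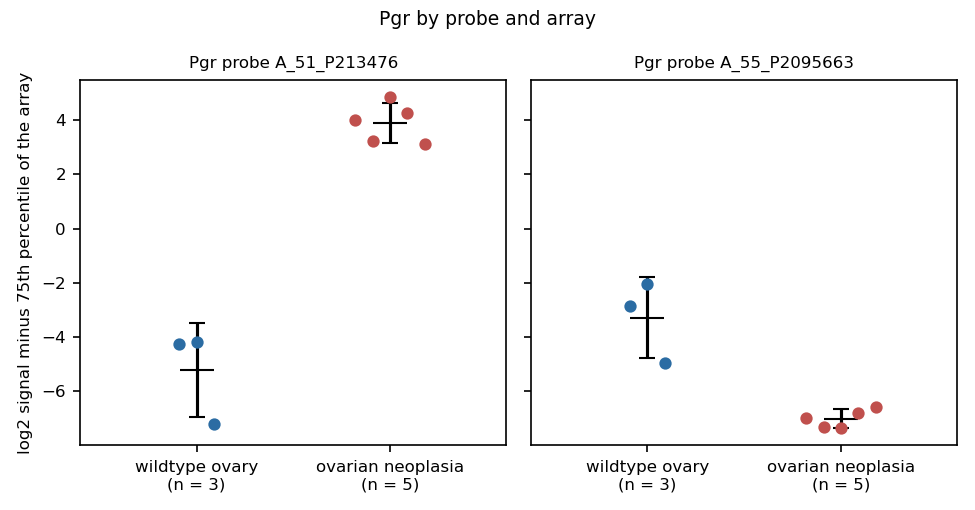
Log2 signal of the 2 Pgr probes minus the 75th percentile of each array, with 1 point per array (3 wildtype, 5 neoplasia) and the mean and SD as a bar. One probe lies near 3.91 in all neoplasias and the other is not well above background there.

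The largest rises were in genes of secreted and barrier proteins that were hardly measured in the wildtype ovary, and the largest falls were in genes of ovarian steroid synthesis, gonadotropin response and the oocyte. Of 25170 tested features, 7635 changed, 4232 of them higher and 3403 lower in the neoplasia, and 5557 changed at least 2-fold, 2710 higher and 2847 lower. Among 15469 features with a gene symbol, 4802 changed, 2660 higher and 2142 lower. Groups did not overlap for 39.0% of the features, against 3.57% expected by chance. The balance of the calls depended on the scaling. Of the calls, 55.4% were higher in the main values, 66.2% with normexp, 50.4% with quantile normalization, 19.9% in the authors' deposited values, which are not scaled between arrays, and 15.4% with spike-in scaling. The share was 67.6% among probes above background on all arrays. The median feature differed by 0.13 on the log2 scale in the main values, 0.21 with normexp, 0.03 with quantile normalization, -0.34 in the authors' values and -0.47 with spike-in scaling, and small changes are to be read against these shifts. The count of changed features was 2826, 3209 and 4033 without wildtype 1, 2 and 3, and 2759 and 3102 changed at least 2-fold without wildtype 1 and 2. It was 1544 with slide row as a block, where the difference rests on neoplasia 5 against the wildtype arrays of its row, and 5298 within that row alone.

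Sprr2g, a member of the small proline-rich proteins of epithelial barriers, was at least 5813-fold higher in the neoplasia. Crisp1, a cysteine-rich secretory protein known from the epididymis, was at least 5662-fold higher, and its relative Crisp3, above background on 1 of 3 wildtype arrays, rose by 13.79 ± 0.50 (SE) on the log2 scale, a value that rests in part on signals below background. The defensins Defb1 and Defb8, antimicrobial peptides, were at least 2188-fold and 380-fold higher. Genes known from the liver were among these rises. Fgb, a fibrinogen chain, was at least 986-fold higher, Lect2 at least 1128-fold and Apoh at least 364-fold. Prl8a2, a prolactin family gene of the decidua, was at least 800-fold higher. Adjusted p for these genes lay between 4.41e-06 and 0.00463.

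Transcripts of the oocyte fell together. Of 24 measured members of the oocyte list, 21 fell, 0 rose and 3 did not pass, and the same 21 count was reached when adjusted over the list alone. Padi6, an oocyte cytoplasmic lattice protein, was at least 220-fold lower, Zar1, a maternal effect gene, at least 106-fold and Zp1, a zona pellucida glycoprotein, at least 66.6-fold, while Oosp1, above background on 1 of 5 neoplasia arrays, fell by 7.20 ± 0.49 (SE) on the log2 scale, a value that rests on signals below background. The list's median was -5.37, or -3.74 with undetected members at their bounds, and 12 members were not above background on any neoplasia array. The list was lower by camera (adjusted p = 4.69e-21; adjusted p = 0.0440 with an estimated correlation). Among probes above background on all arrays, 5 members were left, of which 2 fell, with a median of -0.48. Tdrd5, a germ cell gene among the 10 largest falls, was at least 149-fold lower.

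Granulosa and luteal transcripts fell as well. In the granulosa cell list 12 of 20 members fell and 1 rose, or 13 and 2 when adjusted over the list alone, with a median of -3.41. With slide row as a block 6 fell and 0 rose, with a median of -1.83, which was also that in slide row 2 alone. Inha, the inhibin alpha subunit, fell by 9.36 ± 1.27 (SE), Hsd17b1, which makes estradiol from estrone, fell by 8.54 ± 0.53 (SE), and Fshr, the follicle-stimulating hormone receptor, was at least 33.3-fold lower. Inha was above background on 4 and Hsd17b1 on 1 of 5 neoplasia arrays, so that the fall of Hsd17b1 rests on signals below background. Inhba, an activin subunit, fell by 6.45 ± 1.96 (SE) and lost its call without wildtype 1, 2 or 3 or neoplasia 1, 2, 3 or 4 (largest adjusted p = 0.112). Foxl2, a granulosa transcription factor named after its value was seen, differed by 0.43 and did not pass (adjusted p = 0.118). In the luteal cell list 12 of 20 members fell and 2 rose, also when adjusted over the list alone, with a median of -1.90. Ptgfr, the prostaglandin F receptor, was at least 221-fold lower, Lhcgr, the luteinizing hormone receptor, at least 120-fold lower, and Hsd3b1 and Akr1c18, enzymes that make and inactivate progesterone, fell by 7.90 ± 1.14 and 6.91 ± 0.91 (SE). Both lists were lower by camera (adjusted p = 5.05e-06 and 0.00147; adjusted p = 0.223 for each with an estimated correlation).

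Of the theca and interstitial list, 7 of 12 members fell and 0 rose, or 7 and 1 when adjusted over the list alone, with a median of -0.98 (camera adjusted p = 0.00299; adjusted p = 0.223 with an estimated correlation). Hsd3b6, a steroid dehydrogenase, fell by 9.08 ± 0.61 (SE) and Gli1, a hedgehog target, by 5.52 ± 0.71 (SE), with 2 and 3 of 5 neoplasia arrays above background. Tcf21, above background on 4 of them, fell by 3.37 ± 0.92 (SE) and Star, which carries cholesterol into mitochondria, by 2.17 ± 0.58 (SE), and both lost their call without wildtype 1, 2 or 3 (largest adjusted p = 0.0926 and 0.0929; Tcf21 also without neoplasia 4). Cyp17a1, the androgen-forming enzyme of theca cells, also named after its value was seen, differed by 0.30 and did not pass (adjusted p = 0.498). The count of falls in this list was 2 without wildtype 1, 2 or 3. In the cholesterol synthesis list 4 of 25 members fell and 2 rose, also when adjusted over the list alone (median -1.08, camera adjusted p = 0.00742; adjusted p = 0.693 with an estimated correlation, and 0.0554 by the preset test without neoplasia 5). The exact permutation test of list means, added after the data were seen, did not call it (adjusted p = 0.246). The falls numbered 7 without neoplasia 1, 7 with normexp, 10 with quantile normalization, 12 in the authors' values and 7 with spike-in scaling. Hsd17b7, Dhcr7 and Hmgcs1, enzymes of the pathway, fell by 4.27, 2.92 and 2.55, each on the log2 scale. Hao2, a peroxisomal oxidase among the 10 largest falls and above background on 2 of 5 neoplasia arrays, fell by 8.45 ± 0.56 (SE).

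**Figure D2:**
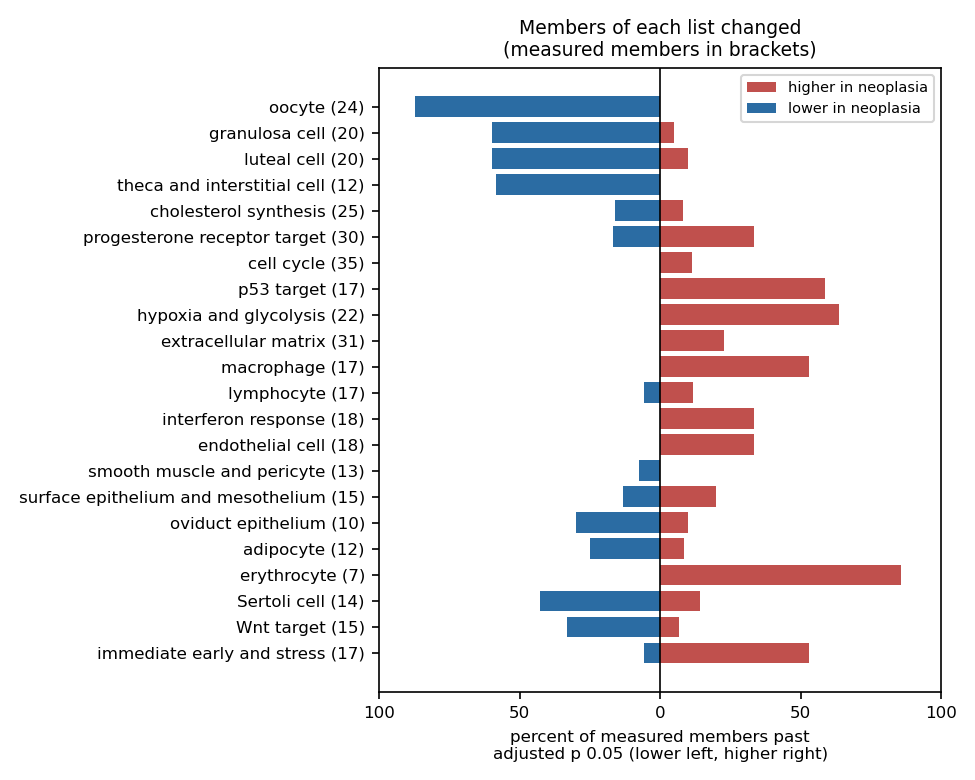
Percent of the measured members of each gene list that passed adjusted p 0.05, with bars to the right for members higher and bars to the left for members lower in the neoplasia, and the number of measured members in brackets. The oocyte list has 21 of 24 members lower and the erythrocyte list 6 of 7 members higher.

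Members of the progesterone receptor target list moved both ways. Of 30 measured members, 10 rose and 5 fell, or 11 and 5 when adjusted over the list alone, and camera did not call the list in the main values (median 0.73, adjusted p = 0.199). Camera called it higher in the authors' values (adjusted p = 0.0110), with spike-in scaling (0.00554) and with slide row as a block (0.0231), where the difference rests on neoplasia 5. Hand2, a stromal transcription factor above background on 2 of 3 wildtype arrays, rose by 10.18 ± 0.89 (SE) on the log2 scale, Prkg2, a cyclic GMP-dependent kinase, by 5.18 ± 0.49 (SE), and Ptgs2, the inducible prostaglandin synthase, was at least 13.5-fold higher. Adcyap1, a neuropeptide induced around ovulation, was at least 14.1-fold lower. By the exact permutation test of list means, the list was 0.97 higher (p = 0.0179, adjusted p = 0.0437). The same test called the oocyte, granulosa, luteal, theca, p53 target, macrophage, erythrocyte and immediate early lists, each with the same adjusted p, the lowest that 56 splits allow here, and no other list. Its rises numbered 6 without wildtype 1 or 2, and its falls 1, 2 and 2 without wildtype 1, 2 and 3. The rises numbered 5 with spike-in scaling.

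Targets of p53 rose, and the cell cycle list was called in some alternatives only. Of 17 p53 targets, 10 rose and 0 fell, or 12 and 0 when adjusted over the list alone, with a median of 1.37 (camera adjusted p = 3.72e-05; adjusted p = 0.270 with an estimated correlation). Pmaip1, a proapoptotic gene, rose by 6.92 ± 0.77 (SE), Cdkn1a, a cyclin-dependent kinase inhibitor, by 3.88 ± 0.27 (SE) and Mdm2, which degrades p53, by 2.45 ± 0.31 (SE). Gtse1, above background on 1 wildtype and 4 neoplasia arrays, rose by 2.85 ± 0.72 (SE), a call lost without wildtype 1 or 2 (largest adjusted p = 0.0952). The rises numbered 6 without wildtype 1 or 2, 4 with spike-in scaling and in slide row 2 alone, and 3 with slide row as a block. Of 35 cell cycle genes, 4 rose and 0 fell, or 1 and 0 when adjusted over the list alone (median 0.50, camera adjusted p = 0.114). Rrm2, a ribonucleotide reductase subunit, rose by 3.89 ± 0.70 (SE). Ccne1, Mcm6 and Pcna rose by 1.91, 1.04 and 0.77, and all 3 lost their call without wildtype 1, 2 or 3 or neoplasia 4 (largest adjusted p = 0.153; Mcm6 and Pcna also without neoplasia 1 or 3). The rises numbered 10 without neoplasia 5, where camera called the list higher (adjusted p = 0.0146), 2 without neoplasia 1 or 3, and 1 without neoplasia 4 or any wildtype array. They numbered 2 with quantile normalization and 1 in the authors' values and with spike-in scaling, where the medians were -0.01 and -0.10. Camera called the list higher with array weights, where 15 rose (adjusted p = 0.0215), and with spike-in scaling (adjusted p = 0.0479). The median turned negative in slide row 2 alone, which sets neoplasia 5 against the wildtype arrays.

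Genes of hypoxia and glycolysis and of the immediate early response rose. Of 22 hypoxia and glycolysis genes, 14 rose and 0 fell, or 18 and 0 when adjusted over the list alone, with a median of 1.91 (camera adjusted p = 1.60e-05; adjusted p = 0.435 with an estimated correlation). Ndrg1 rose by 4.58 ± 0.52 (SE), Ankrd37 by 2.96 ± 0.44 (SE) and Pkm, a pyruvate kinase, by 2.54 ± 0.37 (SE). Egln3, an oxygen-sensing hydroxylase, rose by 3.89 ± 1.19 (SE) and lost its call without wildtype 1, 2 or 3 or neoplasia 1 or 4 (largest adjusted p = 0.119). The rises numbered 4, 5 and 7 without wildtype 1, 2 and 3, 8 with quantile normalization and 5 with spike-in scaling. The list mean was 1.97 higher by the exact permutation test (p = 0.0357), which did not call it (adjusted p = 0.0714). Of 17 immediate early and stress genes, 9 rose and 1 fell, or 10 and 1 when adjusted over the list alone, with a median of 1.32 (camera adjusted p = 0.00119; adjusted p = 0.270 with an estimated correlation). Fos rose by 3.54 ± 0.45, Ccn1 by 3.31 ± 0.27, Junb by 2.36 ± 0.30 and Zfp36, above background on 1 of 3 wildtype arrays, by 2.31 ± 0.25 (SE). The rises numbered 5 without wildtype 1 or 2, and 4 with spike-in scaling.

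Red cell and macrophage transcripts rose. Of 7 erythrocyte genes, 6 rose and 0 fell, also when adjusted over the list alone, with a median of 4.70 (camera adjusted p = 5.65e-05; adjusted p = 0.280 with an estimated correlation). Hbb-bt and Hba-a1, the haemoglobin chains, rose by 6.13 ± 0.58 and 5.43 ± 0.60 (SE), Alas2, the erythroid haem synthesis enzyme, by 5.53 ± 0.78 (SE) and Slc4a1, the red cell anion exchanger, above background on 2 of 3 wildtype arrays, by 4.70 ± 0.58 (SE). Of 17 macrophage genes, 9 rose and 0 fell, or 11 and 0 when adjusted over the list alone, with a median of 1.40 (camera adjusted p = 0.000482; adjusted p = 0.333 with an estimated correlation). Cd14, an endotoxin co-receptor, rose by 4.35 ± 0.49, Msr1 by 2.32 ± 0.43, Fcer1g by 1.82 ± 0.30 and C1qb by 1.66 ± 0.32 (SE). The macrophage rises numbered 6 without any 1 wildtype array, and 3 in the authors' values and 2 with spike-in scaling.

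Of 18 interferon response genes, 6 rose and 0 fell, also when adjusted over the list alone (median 0.86, camera adjusted p = 0.0336; adjusted p = 0.693 with an estimated correlation). The list lost its call without wildtype 3, neoplasia 2 or neoplasia 3 (largest adjusted p = 0.0971), and the exact permutation test did not call it (adjusted p = 0.140). Camera did not call it with normexp (adjusted p = 0.112), among probes above background on all arrays (0.101), with the mean over probes (0.0587), with slide row as a block (0.493) or in slide row 2 alone (0.351). Rsad2, an antiviral enzyme, rose by 2.42 ± 0.30 (SE), Cxcl10, a chemokine, by 2.81 ± 0.70, Zbp1 by 2.50 ± 0.73 and Isg15 by 2.15 ± 0.58 (SE), and the last 3 lost their call without wildtype 2 or 3 (largest adjusted p = 0.102; Zbp1 and Isg15 also without wildtype 1, and Zbp1 without neoplasia 1 or 3). The rises numbered 2, 1 and 1 without wildtype 1, 2 and 3, 3 in the authors' values and 2 with spike-in scaling. Of 17 lymphocyte genes, 2 rose and 1 fell, or 1 and 0 when adjusted over the list alone, and camera did not call the list (median 0.47, adjusted p = 0.486; median -0.05 in the authors' values and -0.13 with spike-in scaling, where 0 rose). Cd4 and Cd3e were higher by 1.19 and 1.01 and Cd79a, a B cell receptor subunit, at least 1.36-fold lower, and all 3 lost their call without wildtype 1, 2 or 3 (largest adjusted p = 0.129; Cd79a and Cd3e also without neoplasia 4, and Cd3e without neoplasia 3). Of 18 endothelial genes, 6 rose and 0 fell, also when adjusted over the list alone, and camera did not call the list in the main values (median 0.73, adjusted p = 0.106). Camera called it higher without neoplasia 1 (adjusted p = 0.0169), in the authors' values (0.0274) and with slide row as a block (0.000196), where the difference rests on neoplasia 5. Esam rose by 1.53 ± 0.22 (SE), and Cdh5, Icam2 and Vwf by 1.54, 1.32 and 1.21, with calls lost without wildtype 1 or 2 (largest adjusted p = 0.122; Vwf also without wildtype 3 or neoplasia 3 or 4). The rises numbered 1, 1 and 3 without wildtype 1, 2 and 3, 3 without neoplasia 4, 2 with quantile normalization and in the authors' values, and 0 with spike-in scaling, where 3 fell.

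Extracellular matrix genes differed between the neoplasias more than between the groups. Of 31 members, 7 rose and 0 fell, also when adjusted over the list alone, while the median was -0.71 and camera did not call the list in the main values (adjusted p = 0.991). With slide row as a block the median was 1.34 and camera called it higher (adjusted p = 4.93e-07), and with array weights 11 fell. Fn1, fibronectin, rose by 4.06 ± 0.29 (SE), Col4a2 and Col4a1, basement membrane collagens, by 1.97 ± 0.33 and 1.91 ± 0.31 (SE), and Mmp2, a matrix protease, by 1.90 ± 0.49 (SE), a call lost without wildtype 1, 2 or 3 (largest adjusted p = 0.0894). The list mean was 4.06 on neoplasia 5, 0.96 to 2.48 on neoplasia 1 to 4, and 2.27 to 2.44 on the wildtype arrays. Without neoplasia 5, 7 members rose and 15 fell. Within slide row 2, which sets neoplasia 5 alone against the wildtype arrays, the median was 1.34. The rises numbered 4 without wildtype 1 or 2, and 4 with quantile normalization and in the authors' values. With spike-in scaling 1 rose and 10 fell.

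Markers of other tissues that an ovary sample can hold varied among the wildtype arrays too. In the main values camera called none of the smooth muscle and pericyte, surface epithelium and mesothelium, oviduct epithelium and adipocyte lists (adjusted p = 0.0725, 0.514, 0.553 and 0.0818). It called smooth muscle lower with normexp (adjusted p = 0.0102), without a filter on dim probes (0.0127), among probes above background on all arrays (0.0131), with array weights (0.0214) and with spike-in scaling (0.0202). It called adipocyte lower with normexp (adjusted p = 0.0184), without that filter (0.0302), with array weights (0.0172) and with spike-in scaling (0.0475), and surface epithelium higher with slide row as a block (0.0231), where the difference rests on neoplasia 5. In the smooth muscle list 1 of 13 fell, or 0 when adjusted over the list alone, which was Cnn1 at -4.75 ± 1.22 (SE, median -0.90). In the surface epithelium list 3 of 15 rose and 2 fell, also when adjusted over the list alone (median -1.09). The keratins Krt8 and Krt18 rose by 4.0 ± 0.78 and 3.52 ± 0.65 (SE), and the epithelial adhesion genes Epcam and Cdh1, above background on 2 and 4 of 5 neoplasia arrays, fell by 3.76 ± 0.96 and 3.18 ± 1.03 (SE). In the oviduct list 1 of 10 rose and 3 fell, also when adjusted over the list alone (median -0.37). Ovgp1, an oviduct glycoprotein, fell by 5.0 ± 1.51 (SE) and ranged from 0.37 to 7.99 on the wildtype arrays, Ccdc39 was at least 5.82-fold lower, and Sprr2f, above background on 1 of 3 wildtype arrays, rose by 5.96 ± 1.72 (SE). In the adipocyte list 1 of 12 rose and 3 fell, also when adjusted over the list alone (median -3.04). Cidea, Plin1 and Lipe fell by 4.87, 3.48 and 1.88 and Pnpla2 rose by 1.59, with Cidea above background on 1 and Plin1 on 4 of 5 neoplasia arrays. The list mean ranged from -1.62 to 2.34 on the wildtype arrays. Of these genes, all but Krt8 and Krt18 lost their call without wildtype 1 (largest adjusted p = 0.167), and all but these and Pnpla2 without wildtype 2. Sprr2f, Plin1 and Lipe also lost it without wildtype 3, Cdh1 without neoplasia 2, 3 or 4, Cidea without neoplasia 1, 3 or 4, Plin1 without neoplasia 3 or 4, and Ovgp1 without any 1 neoplasia. The smooth muscle and adipocyte lists were called lower without wildtype 3 (adjusted p = 0.0217 and 0.00679) and without neoplasia 5 (adjusted p = 0.0201 and 0.0230). Without neoplasia 5, 5 smooth muscle, 5 surface epithelium and 7 adipocyte genes fell, and with spike-in scaling 6, 5 and 7. The smooth muscle falls numbered 3 with normexp and quantile normalization and 4 in the authors' values. The surface epithelium counts were 2 higher and 0 lower without wildtype 1 or 2, and no oviduct gene passed without either of them.

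Of 14 Sertoli cell genes, 6 fell and 2 rose, also when adjusted over the list alone (median -1.42, camera adjusted p = 0.0336; adjusted p = 0.270 with an estimated correlation). Defb19, Cst9 and Aard fell by 4.57 ± 0.76, 4.44 ± 0.81 and 4.07 ± 1.04 (SE), and Tesc rose by 3.71 ± 0.70 (SE). Defb19 was above background on 4 and Cst9 and Aard each on 1 of 5 neoplasia arrays, so that the falls of Cst9 and Aard rest on signals below background. Camera did not call the list with quantile normalization (adjusted p = 0.0555), among probes above background on all arrays (0.195), in the authors' values (0.244), with spike-in scaling (0.0739), with slide row as a block (0.184) or in slide row 2 alone (0.0680). The list lost its call without wildtype 2 or neoplasia 4 (largest adjusted p = 0.0524), the exact permutation test did not call it (adjusted p = 0.0714), Aard lost its call without wildtype 1, 2 or 3 (largest adjusted p = 0.0785), and the falls numbered 3 without any 1 wildtype array. Of 15 Wnt targets, 5 fell and 1 rose, also when adjusted over the list alone, and camera called the list under no setting (median -0.12, adjusted p = 0.301). Ccnd1, cyclin D1, rose by 5.80 ± 0.58 (SE), and Sfrp4 and Rnf43, which restrain Wnt signalling, fell by 4.40 ± 0.90 and 3.92 ± 0.73 (SE), with Rnf43 above background on 2 of 5 neoplasia arrays. Wif1, above background on 1 of them, differed by -2.57 ± 0.84 (SE) with an adjusted p just under 0.05, and it lost its call without any 1 array other than neoplasia 5 (largest adjusted p = 0.172). The falls numbered 2, 3 and 3 without wildtype 1, 2 and 3. The median of the Wnt list was 0.25 with normexp and 0.17 with quantile normalization.

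Slide row as a block, which leaves neoplasia 5 against the wildtype arrays of its row, kept some lists near their main medians and moved others. The medians were -4.86 for oocyte, -1.86 for luteal, -1.09 for theca, -1.36 for cholesterol, -1.11 for Sertoli and -0.40 for Wnt target genes, with 19, 7, 3, 2, 1 and 1 members lower. They were 0.93 for progesterone receptor target, 0.86 for p53 target, 2.49 for hypoxia, 1.66 for macrophage, 0.46 for lymphocyte, 0.21 for interferon, 1.20 for endothelial, 6.08 for erythrocyte and 1.80 for immediate early genes, with 4, 3, 5, 3, 0, 1, 4, 6 and 7 members higher. Cell cycle, surface epithelium, oviduct and adipocyte genes had medians of -0.42, 1.66, 0.58 and 0.74, and the smooth muscle median was near 0. Within slide row 2 alone the medians were the same, apart from 1.0 for progesterone receptor targets.

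The medians of some lists also moved by more than 1.5 times with the scaling or the filter. With normexp the medians were -1.89 for oocyte, -2.26 for granulosa, -0.69 for cholesterol, -0.17 for extracellular matrix, -0.57 for surface epithelium, -0.05 for oviduct, -1.54 for adipocyte, 2.89 for erythrocyte and -0.65 for Sertoli genes. With quantile normalization the progesterone receptor target median was 0.44. In the authors' values and with spike-in scaling, the medians were 0.29 and 0.13 for progesterone receptor target, 0.90 and 0.77 for p53 target, 0.89 and 0.80 for macrophage, 0.39 and 0.26 for interferon, 0.27 and 0.12 for endothelial and 0.85 and 0.72 for immediate early genes. They were -1.54 and -1.58 for theca, -1.19 and -1.32 for extracellular matrix, -1.37 and -1.50 for smooth muscle, -0.91 and -0.97 for oviduct and -0.59 and -0.72 for Wnt target genes, and with spike-in scaling -1.68 for cholesterol and -1.69 for surface epithelium genes. Among probes above background on all arrays, the medians were -1.79 for granulosa, -0.85 for luteal, -0.33 for extracellular matrix and -0.63 for Sertoli genes, with 6 granulosa and 2 Sertoli genes lower.

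**Figure D3:**
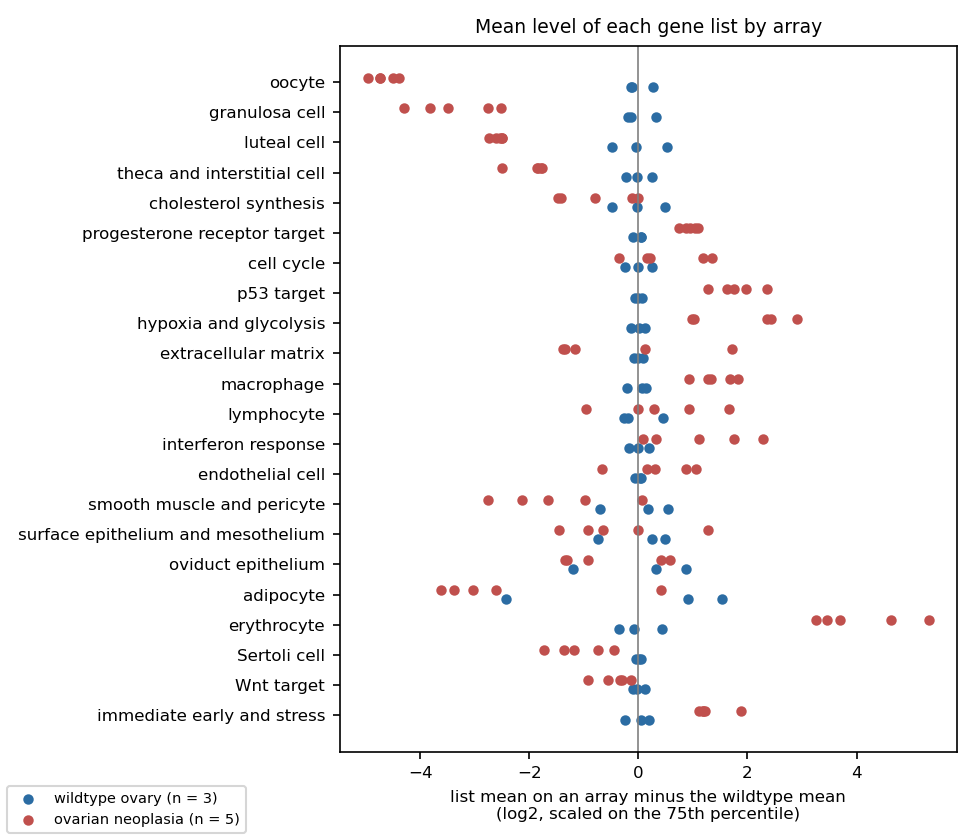
Mean log2 signal of each gene list on each array, minus the mean of the 3 wildtype arrays, with 1 point per array. The 5 neoplasias lie below all wildtype arrays for the oocyte, granulosa, luteal and theca lists, and neoplasia 5 lies apart for extracellular matrix and adipocyte genes.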

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

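The 3 patterns weighed below were chosen after the results were seen. Among their tests, those of a common dilution and of slide row, and the counts over other splits of the arrays, were chosen after the values they measure were known, whereas the marker lists for blood, red cell precursors, uterus and liver were written, with what each explanation would predict, before their values were seen.

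Chance as the origin of the changed features is argued against. Of the 56 splits of the 8 arrays into 3 and 5, 1 gave as many changed features as the real split, namely the real split itself with 7635, and the highest other count was 39. The same held for features changed at least 2-fold, with 5557 in the real split, a highest other count of 39, and 1 split as large. A share of 1 in 56, or 0.0179, is the lowest that these splits can give. They do not separate group from slide row, since neoplasia 1 to 4 were alone in the first row. For gene lists chance can be neither excluded nor shown from the number of calls. The real split gave 12 lists by camera with the preset correlation. Of the 56 splits, 12 gave at least as many, the real one among them, and the highest other count was 16. The count of 16 came from wildtype 1, wildtype 2 and neoplasia 4 against the other arrays. Splits with 2 or 0 wildtype arrays in the group of 3 keep part of the group difference, so they are no clean measure of chance. The member counts of each list, the exact permutation test of list means and the test with an estimated correlation therefore carry more weight than the number of called lists.

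Ovarian cell markers fell in all 5 neoplasias. Dilution of ovarian tissue by other tissue, as the whole cause, needs 1 common fold for all of them, but 78.7% of the 75 measured members of the oocyte, granulosa, luteal and theca lists had a 95% interval that left out the members' median of -3.37. With slide row as a block, 68.6% of the 51 members called lower stayed called lower and their median was -4.84 in neoplasia 5 against -5.30 in the others, but that estimate rests on 1 array and on members called with it, so slide row is left open. A loss of particular cell types, such as oocytes and granulosa cells, and lower expression in the cells that remain may both contribute, and RNA of whole tissue cannot separate them. The genotype and the neoplasia it goes with in the labels remain a candidate explanation.

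Erythrocyte markers rose in all 5 neoplasias. More circulating blood is a possible explanation, since neutrophil and platelet markers rose too, with 6 of 12 members higher, among them Ppbp at least 24.4-fold and S100a8 by 3.72. Their list median was 2.16, or 1.93 with undetected members at their bounds. The erythrocyte median was larger, at 3.90 likewise without a filter on dim probes. Whether 1 common fold covers both lists was not tested. Red cell precursors in the tissue are left open, because the erythroid progenitor list had a median of 0.401 with 2 of 14 members higher. These were Gfi1b, at least 3.47-fold, and Car2, by 2.08, while Klf1 was above background on 1 neoplasia array. Neutrophil genes can also come from infiltrating cells, and haemorrhage and more vessels were not tested apart. No value here shows whether the blood content depends on the genotype or on how the tissue was collected.

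Secretory genes of other organs rose, among them Crisp1, Fgb, Apoh, Defb1 and Prl8a2. Uterine tissue in the samples is argued against by its markers but not excluded. The uterus list had a median of -1.12 (-0.98 with bounds, and -1.89 to -0.29 when 1 array was left out). Of its 11 members 1 was higher, Hoxa13, which was above background on 0 arrays. Hoxa11 was above background on 0 arrays of either group. Hoxa10, which had no fitted value, was above background on 2 of 3 wildtype and 0 neoplasia arrays. However, 3 members, Ltf, Prss28 and Esr1, were above background on all 5 neoplasia arrays. The list median is a difference from wildtype arrays that hold such markers too, with Ltf at 3.44 and 4.46 on wildtype 1 and 2 and -0.31 on wildtype 3. By itself it cannot show how much uterine tissue the neoplasias hold. Liver tissue is left open. The 11 liver markers outside the pattern had a median of 2.03 (1.63 with bounds), but 0.87 without neoplasia 2, and 1 passed, Apoa1. Alb, at -6.70, 6.24, -1.49, -3.19 and 1.00 on neoplasia 1 to 5, did not pass (limma adjusted p = 0.114). On neoplasia 1 it was as low as on the wildtype arrays (-7.16 to -6.62), while Lect2 was at 5.79, Apoh at 1.96 and Apoa1 at 5.87 there. Apoa2, Serpina1a, Ahsg and Cyp2e1 differed by 0.42, 0.22, -0.96 and -3.29 without passing. Slide row is left open too, since all 10 of the 10 largest rises stayed called higher with it as a block, but were picked with neoplasia 5, on which that estimate rests, above every wildtype array. Expression of these genes by the neoplastic cells may be the reason and was not tested.

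Single neoplasia arrays stood apart from the other 4 in 7 of 121 measures tested (94 genes, 22 list means, 4 array measures and the second Pgr probe), or 5.79%, and chance alone gives about 1 in 20. The wildtype group of 3 was not tested. Crisp3 was lowest on neoplasia 2 at 7.01, with the next at 8.53. Defb1 was lowest on neoplasia 5 at 4.25, with the next at 5.93. Ccdc39 was lowest on neoplasia 2 at -7.15, with the next at -5.81. Wif1 was highest on neoplasia 5 at -3.89, with the next at -6.88. The theca and interstitial list mean was lowest on neoplasia 1 at 1.05, with the next at 1.69. The adipocyte list mean was highest on neoplasia 5 at 1.23, with the next at -1.80. The immediate early and stress list mean was highest on neoplasia 5 at 1.68, with the next at 1.02.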

How the results depend on the processing

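The alternatives with spike-in scaling, slide row and exact permutation of list means were chosen after the data were seen. Pgr, taken as 1 value per gene, stayed higher and past the threshold in every alternative that gave a value, from 2.70 (mean over its probes, which moved in opposite directions) to 9.64 on the log2 scale. The filter that needs all 8 arrays above background left it out. On its own, the Pgr probe A_55_P2095663 was at least 2.88-fold lower in the main values. The count of genes changed, 7635 features, was 13801 with array weights, 4767 with spike-in scaling, 1544 with slide row as a block and 2557 at an adjusted p under 0.01, and ran from 2826 to 9957 when 1 array was left out. The count of 5557 changed at least 2-fold was 3606 with normexp, 3561 among probes above background on all arrays and 1544 with slide row as a block, and ran from 2759 to 6872 when 1 array was left out. Camera called 12 lists, 1 with an estimated correlation, and 11 to 14 when 1 array was left out, while fry called 11 and the exact permutation of list means 9, each with the progesterone receptor target list, which camera did not call in the main values and called in some alternatives. The cause of these shifts was not tested, except that slide row as a block leaves the difference to neoplasia 5 alone. The replicate number as a block gave 4682 changed features, 42.9% of them higher, 4678 changed at least 2-fold and 17 lists, among them cell cycle higher and extracellular matrix, smooth muscle, surface epithelium and adipocyte lower, but the numbers did not pair the arrays, since arrays with the same number had correlated deviations (Pearson's r across features) of -0.0541, -0.0308 and -0.00165. With the replicate number as a block, neoplasia 4 and 5 do not enter the difference, since replicates 4 and 5 have no wildtype array. It sets neoplasia 1 to 3 against wildtype 1 to 3. Slide and scan date could not be fitted as blocks, since there was 1 slide and 1 scan. Among the genes given by the naming rule and the lists, results kept direction and side of the threshold in 1993 comparisons with an alternative, lost the call in 260, gained it in 28 and turned direction, for a list by its median, in 28. These were Cd79a at 0.0879 with normexp, and in both slide row alternatives Wif1 at 0.0652 and the medians of extracellular matrix at 1.34, surface epithelium at 1.66, oviduct at 0.58, adipocyte at 0.74 and cell cycle at -0.42. The filter that needs all arrays gave medians of 0.23 for surface epithelium, 0.49 for oviduct, 1.18 for adipocyte and 0.43 for Wnt targets. The Wnt target median was 0.25 with normexp, 0.17 with quantile normalization and with the replicate block, 0.28 with array weights and -0.45 to 0.26 when 1 array was left out. The cell cycle and lymphocyte medians were -0.0121 and -0.0484 in the authors' values and -0.10 and -0.13 with spike-in scaling. Of these 96 genes, 66 passed without any 1 array, and 29, 29 and 20 lost their call without wildtype 1, 2 and 3. Signal over background limits the folds of 322 features called higher and 634 called lower, which were not above background in the dimmer group.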

Other observations

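Gene families, some of which have members in the lists, such as Akr1c18, Nlrp5, Nlrp14, Sprr2f and Slc4a1, were compared after the results were seen, by the stem of the gene symbol, for 269 stems with at least 8 tested members (Fisher's exact test against all 15469 tested symbols, adjusted over the stems). Families and members were singled out after their values were seen. Of 21 Fbxw genes, 12 fell and 0 rose (adjusted p = 0.000565), of which Fbxw14 was at least 45.1-fold lower. Of 15 Pramel genes, 10 fell and 0 rose (adjusted p = 0.000565), and of 13 Nlrp genes, 8 fell and 0 rose (adjusted p = 0.00804), while Nlrp3, of the inflammasome, differed by 1.13 and did not pass. Of 13 Akr genes, aldo-keto reductases, 7 fell and 2 rose (adjusted p = 0.0479), of which Akr1c18 fell by 6.91 on the log2 scale, while Akr1b7 and Akr1b8 rose by 2.70 and 1.91. Of 10 Cacna genes, calcium channel subunits, 6 fell and 0 rose (adjusted p = 0.0479), or 4, 3 and 5 fell without wildtype 1, 2 and 3. With slide row as a block, 1 Akr and 0 Cacna genes fell. Probes of such families can share sequence, and members are not independent. The medians of the Fbxw, Pramel, Nlrp, Akr and Cacna genes stayed negative under each scaling. Among probes above background on all arrays, 10 Fbxw and 2 Nlrp genes were left, with medians of 0.09 and 0.83. That filter leaves out every probe that is not above background in a neoplasia.

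The small proline-rich genes rose as a family, with 6 of 8 Sprr genes higher and 0 lower (adjusted p = 0.0283), and Sprr1a was at least 59.0-fold higher. The Sprr rises numbered 2 without any 1 wildtype array, 3 without neoplasia 4, 4 without neoplasia 1, 2 or 5, 4 with quantile normalization and spike-in scaling, 3 in the authors' values and 2 with slide row as a block. The Rpl and Rps stems, the second of which holds S6 kinases beside ribosomal proteins, had 32 of 49 and 23 of 44 members higher (adjusted p = 2.39e-11 and 1.55e-05), but 0 Rpl genes were higher with quantile normalization, in the authors' values and with spike-in scaling, and the Rpl and Rps medians were -0.06 and -0.09 with quantile normalization, so their direction is not settled. Without wildtype 1, 2 and 3 the rises numbered 0, 0 and 3 for Rpl and 1, 2 and 2 for Rps, and without neoplasia 3 or 4 they numbered 18 and 11. The Slc and Rab stems had 78 of 295 and 23 of 67 members higher (adjusted p = 0.00343 and 0.0283), or 31, 32 and 38 Slc and 3, 6 and 9 Rab members without wildtype 1, 2 and 3 and 14 Rab members without neoplasia 4. In the main values 43 Slc and 7 Rab members were lower. The Slc and Rab medians turned negative in the authors' values and with spike-in scaling. There 35 and 21 Slc genes were higher and 66 and 56 lower, and 4 and 1 Rab genes were higher and 12 and 6 lower.

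The lists added after the data were seen gave these counts without a filter on dim probes. Of 13 decidua and placenta genes 3 rose, Prl8a2, Psg21 and Psg18, and Gcm1 fell (median 0.39, or 0.20 without wildtype 2 and 0.65 without wildtype 3), whereas Tpbpa, of the placental spongiotrophoblast, was above background on 0 arrays. Of 15 epididymis and seminal vesicle genes 6 rose and 0 fell (median 1.31), with Svs1 at least 139-fold higher and Svs5 and Svs6 higher by 7.21 and 8.12, while Lcn8, Lcn9 and Adam7 of the epididymis were above background on 0 arrays. Among the rises in these lists, Prl8a2, Crisp1 and Defb1 were members of the pattern of secretory genes weighed above, seen to rise before the lists were added. Of 16 liver genes 6 rose and 0 fell (median 3.4, or 2.41 with undetected members at their bounds), 5 of which were members of the pattern itself. Of 6 adrenal cortex genes 2 rose (median 1.09), of 7 kidney genes 1 rose and 1 fell (median 0.87), and of 7 pancreas genes 1 rose and 1 fell (median 0.44, or 0.66 without wildtype 1), with Amy2a5, a pancreatic amylase, higher by 6.60. Of 11 uterus genes 1 rose and 2 fell, of 14 erythroid progenitor genes 2 rose and of 12 neutrophil and platelet genes 6 rose. The wildtype ovary itself had 5 of the 11 uterus genes, 10 of the 14 erythroid progenitor genes, 4 of the 12 neutrophil and platelet genes and 7 of the 11 liver genes outside the pattern above background on all 3 arrays.

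The neoplasias were more variable gene by gene than the wildtype ovaries. The median SD per feature was 0.47 on the log2 scale in the neoplasia and 0.20 in wildtype, and the SD was larger in the neoplasia for 84.8% of features, although 5 arrays and 3 arrays give it with different precision. Of 9957 features changed without neoplasia 5, 9954 were also tested with all arrays, and 88.4% of these moved in the same direction in neoplasia 5, with a median ratio of 0.588 to the change in the other neoplasias. The features were picked by their change in those other neoplasias, and both changes share the wildtype arrays. A shared direction and a ratio below 1 therefore follow in part from the choice. Neoplasia 5 was also the only neoplasia in the slide row of the wildtype arrays.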
